A study of Solanum dulcamara with 6 samples.

How the data were processed

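Transcript levels were measured in leaf discs of 6 Solanum dulcamara samples, 3 control and 3 with eggs, with 1 sample of each treatment from each of the populations Erkner, Friesland and Siethen. Samples were grouped by the treatment and population named in their titles, and the replicate number in the titles stood for the population. Per the labels, RNA of several plants was pooled for each array and had an integrity number of 7.3 to 8.0. The deposited scanner files hold intensity values written by Agilent Feature Extraction 11.5.1.1 per the file headers: the processed signal, which is background-subtracted and detrended but not scaled between arrays, and the raw spot and background signals. The authors' value table is on a log2 scale. Each of its columns ranked the spots as the spot median minus the local background median of that array (Spearman 1), and all columns shared a median of 6.87, so the table is background-subtracted and quantile-normalised with no centring of genes. The submitters' processing notes name limma, and its version is not given in the sources used here. The genome build and how the probes' contigs were assembled are likewise not given in the sources used here.

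Each array had 62970 spots, of which 1319 were control spots. After leaving these and outlier-marked spots out, 60151 probes for 28576 contigs remained, and the spots of the 300 probes with more than 1 spot were averaged after scaling. No probe was saturated on any array. Probes exist in both orientations for 5381 contigs and were kept apart as different probes of 1 contig. A description from tomato, potato, Arabidopsis or the KAAS pathway service was present for 42139 probes and absent for 18012. None of the 60665 contig and transcript IDs of the array matched the gene table given with the series, so descriptions are those of the array files. Arrays of the same treatment correlated at r = 0.957 to 0.983 over log2 values and no pair held identical values.

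The analysed value was log2 of the processed signal minus the 75th percentile of its array. Probes were tested for the egg effect when well above background on all 3 arrays of at least 1 treatment, and for populations when well above background on both arrays of at least 1 population. Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with the packages jsonlite 2.0.0 and data.table (version 1.17.8), two-sided, with a Benjamini-Hochberg adjusted p under 0.05. The egg effect was fitted on treatment alone, 3 arrays against 3. The population effect was a moderated F test over 3 populations with treatment as a term and 2 residual degrees of freedom before moderation, and its pairwise contrasts came from the same fit. The egg effect within a population rests on 1 array per treatment and was described without a test. Where a probe was not well above background on any array of a group, the fold is a lower bound, "at least N-fold": the mean of the brighter group against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, on normalised log2 values. The bound holds for this scaling alone. A fitted log2 difference of such a probe depends on signals near the background and is no bound. The median of a list was the same to 3 digits with such members set at their bound.

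Gene lists were defined by word patterns in the descriptions, with 1 probe per gene, the one of highest mean signal, and at least 5 measured genes. They were tested with camera of limma at a preset inter-gene correlation of 0.01, with the estimated correlation beside it, and adjusted over 26 lists. The directional test of fry, also run, asks whether a list moves, on balance, one way and does not compare it with other genes. With the estimated correlation 0 lists passed, the smallest adjusted p being 0.265, while fry called 2. Each list was compared with the other genes among 24067 tested, and some genes belong to several lists. Members past the threshold over all genes tested were counted over all their probes. Pathway terms were also counted as words and word pairs in the descriptions of 10 to 1000 genes, a test added after the values were seen.

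The designs, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. For the egg effect the rule took, among probes past the threshold with 1 sign in all populations and a description, 1 probe per gene, up to 15 genes with the largest increase and 10 with the largest decrease, and 2 members past the threshold in each list. For populations it took the 10 genes with the largest range of population means among probes past the F test, described or not. For the egg effect 5 genes met it, so that other genes were named from those with the largest smallest difference over the 3 populations, from list members adjusted over the list alone, and, for populations, from described genes with the largest range. These were chosen after their values were seen. Control and eggs arrays of the same population deviated together from their group means, with correlations across probes of 0.527 for Erkner, 0.468 for Friesland and 0.335 for Siethen, so the population pairs the arrays and the fit with a population block is given where it changes a call.

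Alternatives were normexp background correction with an offset of 50, quantile and median scaling, the authors' values, no filter and a filter on all 6 arrays, the population block, leaving out each array or population, a variance trend with robust moderation, array weights, slide as a block, another threshold, another probe per gene, and other set tests. The slide, read from the file headers, was tested as a batch: slide 1 held both German control arrays, slide 2 the Friesland control and both German eggs arrays, and slide 3 the Friesland eggs array. No slide term was fitted for populations. The pipeline was tested on simulated data with 200 changed probes. It recovered 76% of 4-fold and 89% of 16-fold changes for 3 against 3 with 10 false of 175 calls, and 77% and 95% with the block with 14 false of 186. The F test recovered 6% and 71% with 3 false of 80 calls, and Friesland against Erkner 36% and 83% with 7 false of 126. Apart from the changed probes, the simulated arrays held no population or slide effect, and they had no floor of signals near the background. The recovered shares thus do not measure the power of these tests on the real arrays. Both of 2 lists shifted by 0.5 were called, along with 1 other list, and 0 lists were called with no shift. With the estimated correlation both shifted lists were called as well. The simulated noise was independent between genes, while the estimated correlation in the real lists was 0.23 for photosynthesis and 0.699 for polyphenol oxidases. The run thus cannot show how often camera at the preset correlation calls unshifted lists of correlated genes.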

Results

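Leaves of bittersweet nightshade (Solanum dulcamara), a wild perennial relative of tomato and potato, were profiled with and without egg clutches of the beet armyworm moth (Spodoptera exigua), whose caterpillars feed on many crop and wild plants. Transcript levels were measured on 6 single-channel Agilent arrays whose probes were designed on bittersweet transcript contigs. The arrays fell into 3 control and 3 eggs samples, with 1 of each from plants raised from seed of Erkner and Siethen in Germany and Friesland in the Netherlands. To obtain eggs, leaves were enclosed overnight with moths of both sexes, 40 of each, and control leaves with 80 males. A disc of 13 mm around the oviposition site was taken 72 h later, once the eggs had been brushed off. Every array carried RNA pooled from several plants. The spread between the 3 arrays of a treatment thus holds both the differences between plant pools and those between the seed origins. The 75th percentile of the processed signal was 363 to 461 on the control arrays and 449 to 557 on the eggs arrays. The small number of arrays limits the precision of every value. The share of probes well above background was 78.2% to 78.3% on the control arrays and 81.2% to 83.2% on the eggs arrays. The eggs array of Friesland also had a lower net signal of the negative control probes, 10.4 against 18.0 to 19.1 on the other 5 arrays. Genes are named by their contig with the description that the array files take from tomato, potato or Arabidopsis, and their place in a genome was not used here.

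The first comparison asked which leaf genes differed in egg-laden leaves 72 h after oviposition, a question set by the study's interest in how the plant reacts to eggs and in the hydrogen peroxide it makes there. In limma's test 5 genes were higher with eggs, and none of them was well above background on any control array. A ribonuclease of the T2 family (A_10269), a class of RNA-degrading enzymes that includes the S-RNases of nightshades, was at least 48.7-fold higher. Ribosomal protein S30 (C_02687), a part of the small ribosomal subunit, was at least 27.6-fold higher. Its signal may come from RNA left by the eggs, which could not be excluded. A Kunitz-type protease inhibitor (A_16248), of a family that blocks the digestive proteases of insects, was at least 8.52-fold higher. A stay-green protein (A_09253), which acts in chlorophyll breakdown, was at least 7.31-fold higher, and TIFY 3B (A_15683), a JAZ-type repressor of the jasmonate pathway, at least 2.20-fold.

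These 5 genes carried the 6 probes past the threshold among the 47460 probes of 24068 contigs tested with limma. At an unadjusted p under 0.05 there were 2572 probes higher and 2351 lower, 10.4% of those tested. The ribonuclease gave a log2 difference of 7.31 ± 0.49 (SE, n = 3 arrays per group, adjusted p = 0.0346), with 7.36 in Erkner, 7.44 in Friesland and 7.14 in Siethen. Its second probe gave 7.37 (adjusted p = 0.0302). The differences of C_02687 (6.64 ± 0.39), A_16248 (5.19 ± 0.32), A_09253 (4.82 ± 0.28) and A_15683 (3.42 ± 0.22) each had an adjusted p of 0.0302 in limma and were positive in all 3 populations. The SD of these 4 genes was 0.18 to 0.24 on the control arrays and 0.35 to 0.79 on the eggs arrays. Their SE and p thus rest partly on the spread of control signals near the background. C_02687 was read by a single probe and had no description from another plant. The other probes of A_16248, A_09253 and A_15683 gave 5.47, 3.48 and 2.13, in the same direction but with adjusted p = 0.0578, 0.278 and 0.278. With the population as a block, limma kept A_10269 alone (adjusted p = 0.0072), while A_16248, A_15683 and C_02687 came to adjusted p = 0.051 and A_09253 to 0.0775. The arrays lay on 3 slides, of which slide 2 alone held both treatments. There the log2 difference was 7.68 for A_10269, 6.52 for C_02687, 5.46 for A_16248, 4.64 for A_09253 and 3.03 for A_15683. Their adjusted p in limma lay between 0.105 and 0.122 within that slide and between 0.0524 and 0.0734 with slide as a block. The control array on slide 2 was from Friesland and its eggs arrays were from Erkner and Siethen, so egg and population differences cannot be told apart within that slide. The fit with slide as a block takes its egg difference from slide 2 alone, so the same limit holds for it. The count past the threshold in limma went to 0 without the control array of Erkner, Friesland or Siethen or the eggs array of Siethen (4743, 4651, 3359 and 2963 probes at an unadjusted p under 0.05), and to 15 without the eggs array of Friesland. It was also 0 on the authors' values (5090), with no filter on dim probes (7924) and among probes well above background on all 6 arrays (4647), a filter that left out all 6 called probes, and with normexp none of the 6 passed. The log2 differences of A_10269, C_02687, A_16248, A_09253 and A_15683 were 3.24, 2.32, 1.31, 1.00 and 0.30 with normexp (adjusted p = 0.0638 to 0.466), all below the bounds given above. On the authors' values they were 5.95, 4.11, 3.46, 3.30 and 1.82, that of C_02687 below its bound, so the bounds hold for the 75th percentile scaling of the processed signal alone.

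**Figure D1:**
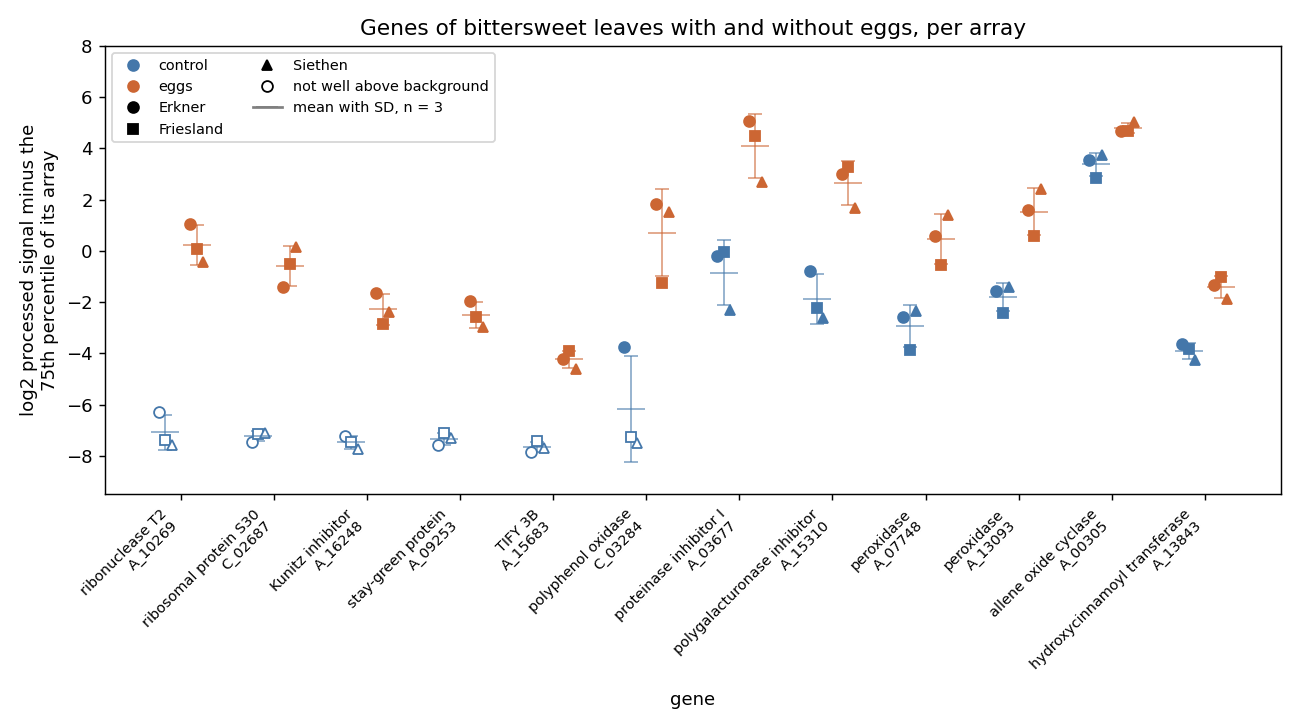
Log2 processed signal relative to the 75th percentile of the array (vertical axis) for 12 genes (horizontal axis), with 1 point per array, bars for the mean and SD of 3 arrays, marker shapes for the populations and open markers where the probe was not well above background. The first 5 genes passed the limma test and their control points are all open, while the 7 to their right were chosen after their values were seen and did not pass over all probes.

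In all, 226 genes were at least 2-fold higher with eggs in each of the 3 populations and 9 were at least 2-fold lower, a count added after the values were seen. At 4-fold the counts were 53 and 0. A polyphenol oxidase (C_03284), an enzyme that turns phenolics into reactive quinones, was higher by 6.88 on the log2 scale and proteinase inhibitor I (A_03677), a classical wound-induced serine protease inhibitor, by 4.93. A polygalacturonase inhibitor (A_15310), which blocks pectin-degrading enzymes of pathogens, was higher by 4.53 and a salicylic acid carboxyl methyltransferase (A_10948) by 5.06. An aquaporin (A_01884), a membrane water channel, was higher by 2.63 and a cysteine-rich extensin-like protein (A_03577) by 4.04. An actin (A_05230) that was not well above background on any control array was at least 13.4-fold higher, and its signal may come from egg RNA. On the lower side stood gibberellin-regulated proteins (C_04177 and A_16974, log2 differences of -1.57 and -1.04) and a subtilisin-like protease (A_09404, -1.31). Of these, C_04177 alone was at least 2-fold lower in every population. A_16974 differed by -0.88 in Erkner, and A_09404 by -0.986 in Erkner and -0.979 in Friesland. Of those higher, C_03284 and A_03577 were well above background on 1 control array and A_10948 on 2, and with normexp the differences of C_03284, A_03577 and A_05230 were 3.51, 1.63 and 1.71 and that of A_09404 -0.79. These genes were chosen after their values were seen, and none passed limma over all probes. Their adjusted p was 0.278 for C_03284, 0.265 for A_03677, 0.171 for A_15310, 0.335 for A_10948, 0.487 for A_01884, 0.131 for A_03577 and 0.0717 for A_05230. Among those lower it was 0.412 for C_04177, 0.428 for A_16974 and 0.318 for A_09404.

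Counted by probe, 432 of 47458 were at least 2-fold higher in every population and 23 lower. With no minimum size the balance was the other way, 10408 probes higher and 11937 lower in every population. With the sign of 1 population turned, the counts at 2-fold were 3 and 1 for Erkner, 144 and 37 for Friesland and 6 and 2 for Siethen. With no minimum size they were 3265 and 3783, 5365 and 5041, and 3547 and 4112. Words of the descriptions were tested for enrichment among the 226 genes with Fisher's exact test over 2164 terms. This test treats genes as independent, and the 226 were chosen on the same arrays. Its p thus holds no spread between arrays or plants. Members of the peroxidase superfamily, which form and use hydrogen peroxide at the cell wall, made up 9 of 32 genes with that term (adjusted p = 2.44e-08). GDSL esterases, a family with cuticle-building members, made up 5 of 39 (adjusted p = 0.0224), and non-specific lipid transfer proteins, which carry lipids to the surface, 4 of 22 (adjusted p = 0.0262). The wider terms did not pass, esterase lipase with 5 of 58 (adjusted p = 0.077) and lipid transfer with 4 of 38 (adjusted p = 0.118). Each of the 5 terms past the threshold referred to these 3 families. Normexp background correction lowered the probe count from 432 to 128 and the authors' values to 269.

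Anti-herbivore proteins were among the lists that camera called higher with eggs at the preset correlation. All 5 polyphenol oxidases had positive differences, with a median of 1.15 on the log2 scale (limma camera, preset correlation, adjusted p = 7.66e-04, and adjusted p = 0.511 with an estimated correlation). Both C_03284 (6.88 ± 1.25, SE) and C_03285 (4.93 ± 0.97, at least 6.89-fold) passed when adjusted over the list alone. Over all genes tested in limma 0 passed, with 2 at an unadjusted p under 0.05. The 56 proteinase inhibitors, which slow the digestion of feeding insects, had a median of 0.09 and 35 positive members (camera adjusted p = 0.022, and adjusted p = 0.265 with an estimated correlation). Of these, A_16248 and A_03677 passed adjusted over the list alone. The probe of A_16248 in the list had adjusted p = 0.0578 over all genes tested, where only its other probe passed. The 74 genes of apoplastic peroxidases and ROS producers, enzymes that make or use reactive oxygen species outside the cell and the group nearest to the study's interest in hydrogen peroxide, had a median of 0.10 and 47 positive members (camera adjusted p = 0.00721, and adjusted p = 0.361 with an estimated correlation). Members adjusted over the list alone were 12 higher and 1 lower against 0 over all genes tested in limma, with 16 higher and 5 lower at an unadjusted p under 0.05. Examples were the peroxidases A_07748 (log2 3.42 ± 0.60), A_13093 (3.33 ± 0.51) and A_17176 (2.01 ± 0.24), and an amine oxidase (A_12911, 0.59), an enzyme type that releases hydrogen peroxide. Another peroxidase, A_11063, was lower (-0.84, adjusted p = 0.0487 over the list). Within slide 2 the medians were 1.79, 0.29 and 0.02 for the polyphenol oxidases, inhibitors and peroxidases (camera adjusted p = 5.92e-06, 0.00167 and 0.0466). With slide as a block the adjusted p was 5.45e-05, 0.00763 and 0.0467, and for these and all later lists slide 2 mixes egg and population differences. The block fit gave the same medians, as its egg difference comes from slide 2 alone, and is no separate check. The inhibitor call was lost with the population block (adjusted p = 0.0528), with no filter on dim probes (0.0707), on probes above background on all 6 arrays (0.0933) and with the smallest-p probe of each gene (0.0618). Leaving out arrays ended it without the control array of Friesland (0.239) and without the eggs array of Erkner (0.0587), and with the block without both arrays of Friesland (0.151) or Siethen (0.0832). The median of the proteinase inhibitors, 0.04 with normexp, was 0.22, 0.01 and 0.15 without the control arrays of Erkner, Friesland and Siethen and 0.23 and 0.03 without the eggs arrays of Friesland and Siethen. The peroxidase call was lost without the control array of Erkner (0.0545), with no filter (0.722) and on probes above background on all 6 arrays (0.0689), and with the block without both arrays of Erkner (0.0889). The peroxidase median turned to -0.01 with normexp while the test still pointed higher. It was 0.03, 0.17 and 0.19 without the control arrays of Erkner, Friesland and Siethen and 0.04 and 0.07 without the eggs arrays of Friesland and Siethen.

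Genes of jasmonate biosynthesis and signalling, which make and relay the main hormone of the response to chewing insects, were called higher as a list by camera at the preset correlation. The 43 members had a median log2 difference of 0.34 and 30 positive values (camera adjusted p = 1.65e-06, and adjusted p = 0.265 with an estimated correlation), and limma's fry also called the list (adjusted p = 0.0377). Members passing adjusted over the list alone were 8, all higher, with A_15683 among them. Its probe in the list (2.13) had adjusted p = 0.278 over all genes tested, where only its other probe passed. They included the biosynthetic enzymes allene oxide cyclase (A_00305, 1.43 ± 0.25) and 12-oxophytodienoate reductase (A_10814, 0.93 ± 0.17), the GH3-type jasmonate conjugating enzyme A_12374 (0.87 ± 0.22) and the repressors JAZ3 (A_13903, 1.29 ± 0.29) and JAZ2 (C_01591, 0.61 ± 0.15). The other 2 called beside A_15683 were C_06686 (at least 14.9-fold) and C_06685 (at least 4.90-fold), described as anthocyanidin synthase in tomato and as a jasmonate-regulated gene in Arabidopsis, and so also counted in the flavonoid list. Within slide 2 the median was 0.44 (camera adjusted p = 2.17e-05, and 9.4e-05 with slide as a block). With normexp the median was 0.19 and on probes above background on all 6 arrays 0.22, with the call kept.

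The 97 genes of phenylpropanoid and lignin biosynthesis, which supply phenolic defence compounds and the stiffening polymer of cell walls, had a median of 0.33 with 69 positive (camera adjusted p = 9.32e-06, and adjusted p = 0.361 with an estimated correlation). A hydroxycinnamoyl transferase (A_13843, 2.50 ± 0.27) passed adjusted over the list alone. Over all genes tested in limma 0 passed, with 21 higher and 6 lower at an unadjusted p under 0.05. Phenylalanine ammonia lyase (A_02623), the entry enzyme of the pathway, differed by 0.51 ± 0.12 without passing. The 49 genes of terpenoid biosynthesis had a median of 0.13 with 33 positive (camera adjusted p = 0.0197, and adjusted p = 0.265 with an estimated correlation, fry adjusted p = 0.0377). An ocimene synthase (A_14420), the enzyme of a common leaf volatile, passed adjusted over the list alone at 0.82 ± 0.12. Over all genes tested in limma 0 of the terpenoid genes passed, with 5 higher at an unadjusted p under 0.05. Within slide 2 the phenylpropanoid median was 0.29 (camera adjusted p = 2.8e-04, and 5.49e-04 with slide as a block) and the terpenoid median 0.15 (0.0771, and 0.118 with slide as a block). The terpenoid call was also lost without the control array of Friesland (adjusted p = 0.0762) and with the block without both arrays of Friesland (0.0574). With normexp the medians were 0.15 for phenylpropanoid and 0.06 for terpenoid genes, and the phenylpropanoid median was 0.20 without the control array of Erkner and 0.21 without the eggs array of Siethen, with the calls kept.

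Genes of the leaf surface and the cell wall formed a further pair of lists that camera called higher at the preset correlation. Limma's fry called neither (adjusted p = 0.364 for the wall and 0.354 for the surface list). The 206 genes of cell wall modification had a median of 0.15 with 126 positive (camera adjusted p = 8.09e-04, and adjusted p = 0.517 with an estimated correlation). The 100 epidermis, cuticle and trichome markers had a median of 0.11 with 63 positive (camera adjusted p = 8.09e-04, and adjusted p = 0.517 with an estimated correlation). In the wall list A_15310 (4.53 ± 0.61), A_03577 (4.04 ± 0.49) and an expansin-like protein (A_03857, 1.47 ± 0.16), of a family that loosens walls, passed adjusted over the list alone. A_15310 entered by the word polygalacturonase, although it is described as an inhibitor. In the surface list A_10079 (5.27 ± 0.82), a lipid transfer protein (C_06707, 1.67 ± 0.17) and a ketoacyl-CoA synthase (C_01584, 1.37 ± 0.21), which elongates the fatty acids of wax, did so. A_10079 is described as a diacylglycerol O-acyltransferase and entered by a word match in another of its descriptions. Over all genes tested 0 members of either list passed limma, with 31 higher and 4 lower wall genes and 14 higher surface genes at an unadjusted p under 0.05. Within slide 2 the medians were -0.04 and 0.02 (camera adjusted p = 0.187 and 0.155, and 0.141 and 0.153 with slide as a block), so neither call held there, although the test of the wall list still pointed higher. The surface list also no longer passed with array weights (adjusted p = 0.0596). With normexp the medians were 0.04 for the wall and 0.01 for the surface genes with the calls kept, the wall median was 0.05 without the control array of Erkner, and the surface median was 0.18 without the control array of Friesland or the eggs array of Erkner.

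Most photosynthesis genes had negative and most ribosomal protein genes positive differences, each by a small amount, and the ribosomal members did not move as 1 group. Of 128 photosynthesis genes 107 had negative differences, with a median of -0.26 (camera adjusted p = 1.65e-06, and adjusted p = 0.522 with an estimated correlation). A PsbP-like protein of photosystem II (DC_00702) differed by -0.56 ± 0.15 and a light-harvesting-like protein (A_08819) by -0.46 ± 0.13, neither past the threshold. Single members passing limma were 0 over all genes tested and 0 adjusted over the list alone, with 14 lower and 3 higher at an unadjusted p under 0.05. Of 345 ribosomal protein genes 258 had positive differences, with a median of 0.24 (camera adjusted p = 1.66e-05, and adjusted p = 0.599 with an estimated correlation). C_02687, whose signal may come from egg RNA, was the single member past the threshold, both over all genes tested and adjusted over the list alone. At an unadjusted p under 0.05 there were 11 higher and 21 lower. Of these ribosomal genes, 143 cytosolic members had a median of 0.306, with 132 positive and 11 negative. The 103 plastid-type members had a median of -0.201, with 45 positive and 58 negative. The medians of the 2 full lists kept their sign under the quantile, median, normexp and authors' scalings, but that of photosynthesis was -0.16 with quantile normalization and -0.15 on the authors' values. Without the eggs array of Friesland the medians were -0.40 for photosynthesis and 0.36 for ribosomal proteins, and with the block and both arrays of Siethen left out the ribosomal median was 0.12. In Erkner, Friesland and Siethen the medians were -0.26, -0.15 and -0.36 for photosynthesis and 0.11, 0.12 and 0.43 for ribosomal proteins. Within slide 2 they were -0.54 for photosynthesis and 0.49 for ribosomal proteins (camera adjusted p = 5.92e-06 and 7.37e-10, and 5.09e-06 and 8.85e-09 with slide as a block).

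**Figure D2:**
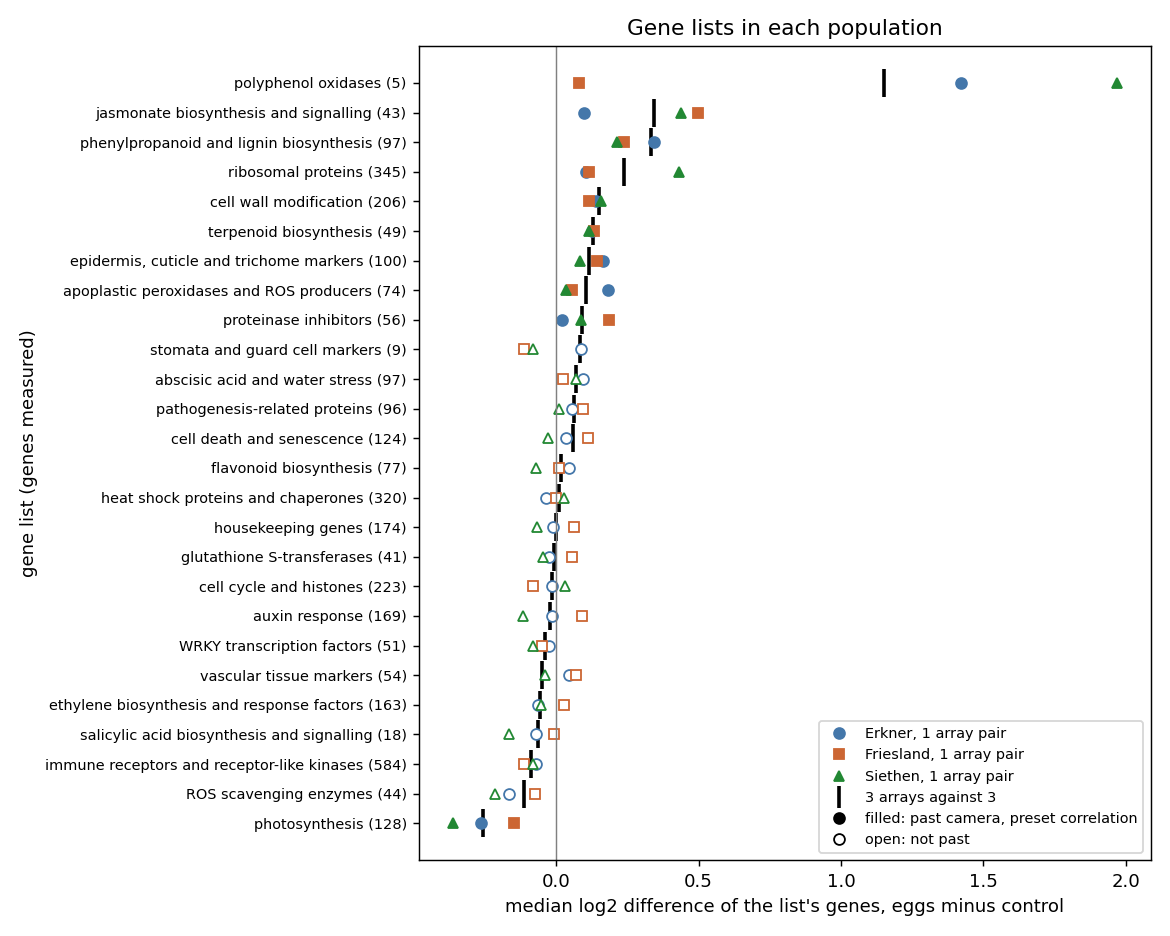
Median log2 difference, eggs minus control, of the measured genes of 26 lists (horizontal axis in log2 units, number of genes beside each name), with 1 marker per population from a single pair of arrays and a black tick for 3 arrays against 3. The 10 lists past the camera test with a preset correlation are filled, from the polyphenol oxidases at 1.15 to photosynthesis at -0.26.

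The other 16 lists did not pass camera. Enzymes that scavenge reactive oxygen species came closest on the lower side, with a median of -0.11 over 44 genes (adjusted p = 0.071, and adjusted p = 0.599 with an estimated correlation). With the population as a block the list passed at adjusted p = 0.0464, and at 0.51 with an estimated correlation it did not. The 124 cell death and senescence genes had a median of 0.06 (0.071), and A_09253 passed over all genes tested and adjusted over the list alone. The 96 pathogenesis-related proteins had a median of 0.06 (0.115), and a chitinase (A_12117, 2.96), of a class that degrades fungal and insect chitin, and a thaumatin-like protein (A_13374, 1.26) passed adjusted over the list alone. The 584 immune receptors and receptor-like kinases had a median of -0.09 (0.115), 97 abscisic acid and water stress genes 0.07 (0.252), 77 flavonoid genes 0.02 (0.265) and 54 vascular markers -0.05 (0.359). Adjusted over the list alone, 4 flavonoid genes were higher, C_06686, C_06685, an anthocyanidin glucosyltransferase (A_10342, 2.78) and another anthocyanidin synthase (A_12641, 2.45), as was a phloem lectin (A_00247, 1.76) among the vascular markers. The median was -0.07 for 18 salicylic acid genes (0.711), -0.06 for 163 ethylene genes (0.711), 0.01 for 320 heat shock proteins and chaperones (0.756), -0.02 for 223 cell cycle genes (0.764), -0.02 for 169 auxin genes (0.764), -0.04 for 51 WRKY factors (0.8) and -0.01 for 41 glutathione S-transferases (0.8). The 174 housekeeping genes had a median near 0 (-0.00103, adjusted p = 0.764), with A_05230 alone past the threshold over the list. Among 9 stomata and guard cell genes, with a median of 0.08 (0.711), a pair of epidermal patterning factor-like peptides (C_04053, -0.68, and A_09439, -0.65) was lower adjusted over the list alone, and the test pointed lower. Median, mean and test also differed in sign for the salicylic acid, ethylene, WRKY, cell cycle, auxin, housekeeping, vascular and glutathione S-transferase lists. Apart from A_09253, limma called 0 members of these 16 lists over all genes tested. Unadjusted p under 0.05 were held by as few as 1 glutathione S-transferase and as many as 33 higher and 20 lower chaperones and 21 higher and 32 lower receptors.

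The egg differences of Erkner and Siethen were more alike than either was to those of Friesland. Across 47458 probes the log2 differences of Erkner and Siethen correlated at Pearson r = 0.619, those of Erkner and Friesland at 0.295 and those of Friesland and Siethen at 0.308. The sign was the same in all 3 populations for 47.1% of probes, against 25% for 3 independent differences with either sign equally likely. The array pairs of Erkner and Siethen both ran from slide 1 to slide 2. Shared egg and shared slide differences thus cannot be told apart in that share. The polyphenol oxidase medians were 1.42 in Erkner, 1.97 in Siethen and 0.08 in Friesland, though C_03284 and C_03285, neither well above background on the Friesland control array, were also higher there. The jasmonate medians were 0.10 in Erkner, 0.44 in Siethen and 0.50 in Friesland. At least 2-fold higher were 1734 probes in Erkner, 2095 in Friesland and 2428 in Siethen, against 526, 1108 and 810 lower. These correlations run across genes, which are not independent replicates, and with 1 array per treatment and population the differences between populations were not tested.

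The other comparison the design allows is between the seed origins, over control and eggs leaves alike. A serine carboxypeptidase (C_05668), of a family of protein- and acyl-processing enzymes, was at least 833-fold higher in Siethen than in Erkner and was not well above background in Friesland either. An alcohol dehydrogenase (A_14391), measured in Erkner and Siethen, was at least 64.4-fold higher in Erkner than in Friesland. Cytochromes P450 (DC_00451 and C_01522), oxidising enzymes of much of plant specialised metabolism, were at least 51.3-fold and 50.9-fold higher in Friesland than in Erkner. A helicase (A_08126) and a Kunitz-type trypsin inhibitor (A_16435) were at least 22.5-fold and 26.1-fold higher, and none of these 4 genes was well above background in Siethen or Erkner. A Mutator-like transposase (A_11494), from a family of mobile elements, was at least 24.5-fold higher in Erkner than in Siethen, where it was not well above background. An AP2-like transcription factor (C_06561) and a UDP-glucosyltransferase (C_05911) were measured in all 3 populations and ranged over 5.95 and 5.03 on the log2 scale between Siethen and Friesland. Other processing lowered these ranges, at the smallest to 4.5 and 3.0. For C_05668, A_14391, DC_00451 and C_01522 the smallest log2 ranges were 7.2, 3.6, 3.3 and 3.3, against bounds of 9.7, 6.0, 5.7 and 5.7. For A_08126, A_16435 and A_11494 they were 2.2, 2.3 and 2.1, against bounds of 4.5, 4.7 and 4.6. The bounds are thus no floor under other processing.

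The limma F test over the 3 populations with treatment as a term called 169 of 48449 probes, on 143 contigs, and 11009 had an unadjusted p under 0.05. The adjusted p was 0.00986 for C_05668, 0.0133 for A_14391, 0.0437 for DC_00451, 0.0489 for C_01522, 0.00986 for A_08126, 0.0271 for A_16435, 0.00986 for A_11494, 0.0198 for C_06561 and 0.0128 for C_05911. The 10 genes with the largest range also held A_00489, at least 31.7-fold higher in Friesland than in Siethen (adjusted p = 0.0117), and 4 contigs without a description. Of these, C_00185 was above background in Friesland alone (at least 51.9-fold), C_04837 and DC_01088 in Erkner and Siethen (at least 120.4-fold and 38.9-fold) and A_16071 in Friesland and Siethen (at least 20.5-fold). With other processing their log2 ranges fell to 3.3, 4.1, 2.5 and 2.1, and that of A_00489 to 2.7, all below their bounds. In 90 of the 169 probes, 53.3%, the signal was not well above background on either array of at least 1 population. None of the 26 lists was enriched among the 73 genes past the F test of 24494 (Fisher's exact test, adjusted p = 1 for each list, smallest unadjusted p = 0.113 for glutathione S-transferases).

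**Figure D3:**
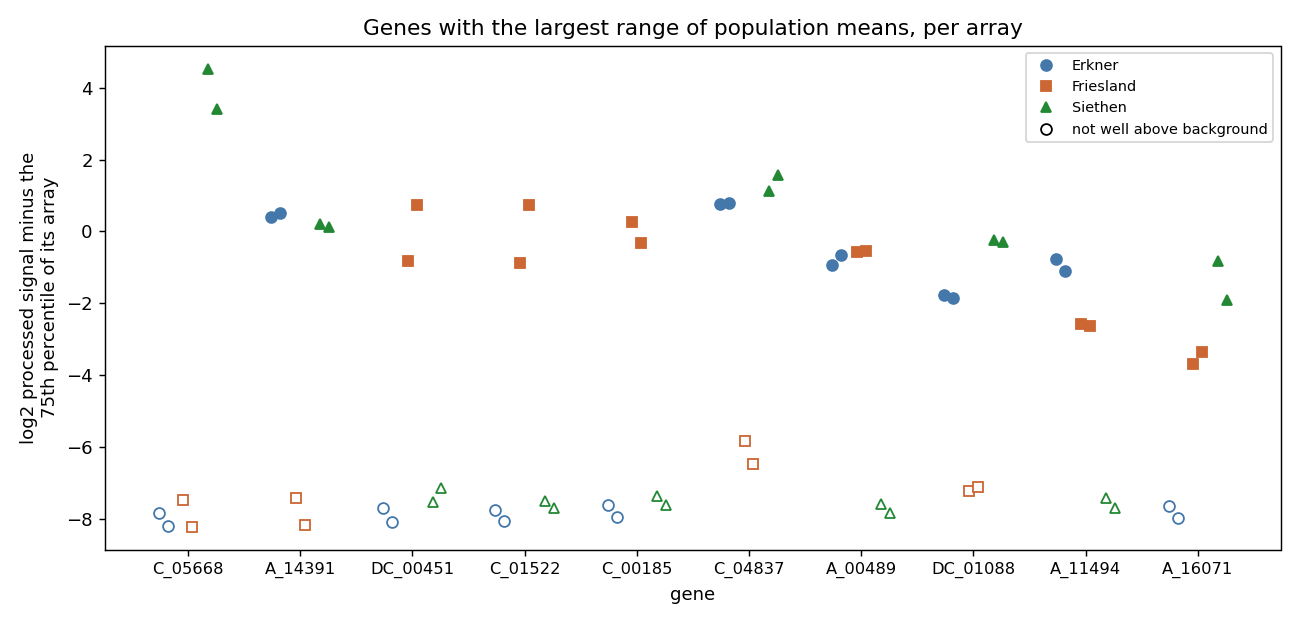
Log2 processed signal relative to the 75th percentile of the array (vertical axis) for the 10 genes with the largest range of population means (horizontal axis), with the control array on the left and the eggs array on the right of each pair and open markers where the probe was not well above background. Control and eggs arrays of a population lie close together and populations far apart, which follows partly from the choice of genes by the F test and the range. The largest range, 11.98 log2 units at C_05668, rests on signals not well above background in Erkner and Friesland, and its bound is 9.70.

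Pairwise, Friesland stood apart. Against Erkner limma called 366 probes, 231 higher and 135 lower in Friesland, and against Siethen 314, 155 higher and 159 lower, while Siethen against Erkner gave 6, 2 higher and 4 lower, with 5435 probes at an unadjusted p under 0.05. The split against Erkner was 136 higher and 146 lower with quantile normalization and 224 and 204 on the authors' values. Friesland was higher in both contrasts for 95 probes and lower in both for 99. Independent lists would share 0.739 and 0.443, unchanged groups simulated against the same arrays shared 0 at most in 20 sets, and part of the excess may come from the shared Friesland arrays. The simulated sets hold no effects and the independent lists no shared arrays, so neither measures that part. Friesland lay on slides 2 and 3 and the other populations on slides 1 and 2, so slide and Friesland could not be separated, while Siethen and Erkner were compared within slides. Without any single Erkner or Siethen array the F test called 0 probes (5985 to 8857 at an unadjusted p under 0.05), as did each pairwise contrast (2498 to 11156). Without the control or the eggs array of Friesland the F test called 29 and 58, Friesland against Erkner 143 and 202, and Friesland against Siethen 158 and 140.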

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

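The count of probes at least 2-fold different in every population, the splits run with the population block, trend and robust moderation, and the count of population probes without the Friesland eggs array are tests chosen only after the result was seen. In 10 of the 26 gene lists the median egg difference was positive in 1 population and negative in another. With 1 pair of arrays per population these differences were not tested, and none of the 10 lists passed camera. The gap between the highest and lowest population median was 0.205 on the log2 scale for auxin response (0.0902 in Friesland, -0.115 in Siethen) and 0.201 for stomata and guard cell markers (0.0886 in Erkner, -0.112 in Friesland). It was 0.14 for cell death and senescence (0.112 in Friesland, -0.0282 in Siethen) and 0.129 for housekeeping genes (0.0624 in Friesland, -0.0666 in Siethen). Flavonoid biosynthesis had a gap of 0.117 (0.0448 in Erkner, -0.0719 in Siethen), cell cycle and histones 0.114 (0.0313 in Siethen, -0.0827 in Friesland) and vascular tissue markers 0.108 (0.0691 in Friesland, -0.039 in Siethen). Glutathione S-transferases had 0.105 (0.0574 in Friesland, -0.0475 in Siethen), ethylene biosynthesis and response factors 0.0915 (0.0273 in Friesland, -0.0642 in Erkner), and heat shock proteins and chaperones 0.0644 (0.0281 in Siethen, -0.0363 in Erkner).

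Probes at least 2-fold different in every population were nearly all higher with eggs, 432 against 23, while with no minimum size 10408 probes were higher and 11937 lower in every population. Dim probes alone do not account for this, since the 11865 brightest of the tested probes held 63 higher and 4 lower, a ratio of 15.8 (94% higher, exact 95% interval 85.4% to 98.3%), nor does the scaling, the smallest ratio under the median, quantile, normexp and authors' values being 11.8. RNA left by the eggs stays open: genes without a plant description made up 11.1% of the 226 genes (25, exact 95% interval 7.29% to 15.9%) against 21.4% of all 24067, but all probes were designed on bittersweet contigs, where egg RNA would bind mainly conserved genes, which have descriptions, so a low share decides nothing. Of the 47 genes among them not well above background on any control array 4 had no description, and C_02687, a ribosomal protein known only from the pathway service, and the actin A_05230, both of kinds that every animal cell makes, may come from egg RNA. The slides stay open as well, since each eggs array lay on another slide than the control array of its population. The pairs of Erkner and Siethen ran from slide 1 to slide 2 and that of Friesland from slide 2 to slide 3. With the sign of Friesland turned, 144 probes were higher and 37 lower at 2-fold. Egg and slide differences thus cannot be told apart in these counts. A response of the leaf to the eggs is the candidate biological explanation, as a hypothesis found and tested on the same data.

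Egg differences of Erkner and Siethen resembled each other (r = 0.619) more than those of Friesland (0.295 and 0.308), and a seed-origin difference and the slides cannot be told apart here. In 0 of the 3 populations did both arrays share a slide, the pairs of Erkner and Siethen both ran from slide 1 to slide 2, and that of Friesland from slide 2 to slide 3. Signals near background could account for part of the gap: in the 11865 brightest probes the correlation of Erkner with Siethen exceeded the mean of the others by 0.129 (0.699 against 0.58 and 0.561), against 0.318 over all probes. The gap became smaller but stayed above 0 there, which leaves this explanation undecided. A true difference between seed origins in the response was not tested.

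Of the 169 probes called between populations, 90 (53.3%) were not well above background on either array of at least 1 population, 23 in Friesland, 58 in Erkner and 59 in Siethen. A slide effect of the Friesland eggs array as the cause of every such probe is argued against, since the F test on all 48449 probes without that array still called 58, of which 38 had Friesland apart and a population not well above background. For the other probes it stays open: of 126 with Friesland apart 24 passed without that array, and that 118 (93.7%) differed at least 4-fold between control arrays decides nothing, as the F test chose them partly on those arrays, while the Friesland control also lay on another slide than the other controls. Without its eggs array Friesland rests on its control array alone, and the spread in that F test comes from the arrays of Erkner and Siethen. Sequence variants under a single probe stay open: other probes of the same contig and orientation had the same direction and at least 50% of the size in 93 of 125 pairs, 74.4% (exact 95% interval 65.8% to 81.8%). Genes absent or silent in some seed origins are a candidate biological explanation, which these arrays cannot separate from variants spanning a whole contig.

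The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 6 probes and the others 0 at most, so that 1 of the 10 reached 6. For lists the real split gave 10 and the highest other 6, for the control arrays of Erkner and Friesland with the eggs array of Friesland against the rest. The numbers pair the arrays, and the 3 other splits that part all pairs mix treatments. They gave 0 probes each in limma (361, 1261 and 285 at an unadjusted p under 0.05) and 4, 5 and 2 lists, and 0 with the population block alone or with trend and robust moderation, where the real split gave 1 and 294. Each of these 3 splits swaps the labels of 1 pair, so any true egg difference adds to their spread. Their counts of 0 thus cannot show how many of the 294 calls are false. At an unadjusted p under 0.05 the split with both Friesland arrays and the control array of Siethen on 1 side held 6676 probes against 4923 for the real split, and 0 past the threshold in limma.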

How the results depend on the processing

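Chosen after the data were seen were the random slide block, the fit within slide 2, the population block with a trend and robust moderation or with normexp, Fisher's exact test of lists, and the count of probes at least 2-fold higher in every population. The 6 probes of the egg effect became 0 on the authors' values, with no filter, with the filter on all 6 arrays and at an adjusted p under 0.01, 1 with the replicate block, 23 with trend and robust moderation, 53 with array weights, 25 with slide as a block and 3 within slide 2, of which none was among the 6 in either slide fit. Leaving out single arrays gave 0 to 15. With the replicate block, leaving out both arrays of Erkner, Friesland or Siethen gave 0, 362 (351 higher, 11 lower) and 0 (5283 and 5233 probes at an unadjusted p under 0.05 in limma for the counts of 0), adding trend and robust moderation 294 (245 higher, 49 lower) and adding normexp 149 (137 higher, 12 lower). Normexp alone gave 6 probes, none shared with the main 6, quantile normalization 7 with 4 shared, and median scaling, the random slide block and a 2-fold minimum 6. Of 26 lists 10 passed, against 0 with an estimated correlation and 2 with fry, 7 to 13 under every other alternative and 9 to 12 with single arrays left out. The replicate block ended the call of proteinase inhibitors (adjusted p = 0.0528), called ROS scavenging enzymes (0.0464, and 0.51 with an estimated correlation) and ended that of 4 of 5 genes of the egg effect, and it changed no other list or egg-effect call. The 432 probes became 128 with normexp, 269 on the authors' values and 229 with the filter on all 6 arrays, and the mean correlation between populations ranged from 0.282 to 0.475 around 0.407. The 169 probes of the population effect became 1624 with normexp, 20 with no filter, 46 with the filter on all 6 arrays, 1481 with trend and robust moderation and 0 to 58 with single arrays left out. Friesland against Erkner fell from 366 to 15 and Friesland against Siethen from 314 to 28 with no filter, the latter reached 714 on the authors' values, and Siethen against Erkner fell from 6 to 0 under both. The filter on all 6 arrays leaves out genes off in 1 group by construction, fewer arrays lower the degrees of freedom, and for the rest the cause was not tested. No named gene changed sign and no called list turned direction in camera, though the peroxidase median turned negative with normexp and the cell wall median with slide as a block and within slide 2: 5 egg genes kept their call in 40 of 110 values and lost it in 70, 66 further genes stayed below the threshold in 1395 of 1493 and passed in 98, 10 lists kept it in 190 of 229, and 19 population genes in 142 of 249. Signals near background limit the sizes and the spread used by the tests, since all 5 called egg genes rest on control signals not well above background. No slide term was run for populations.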

Other observations

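The egg-effect settings with the population as a block, with a variance trend and robust moderation or with normexp, and the test of the ribosomal proteins were chosen only after the result was seen. With the population block, trend and robust moderation limma called 294 probes of 206 genes, 168 of them described, and 130 probes, 120 of them higher, were also called with the block and normexp. Enzymes at the start of aromatic amino acid synthesis were among the genes higher with eggs. A DAHP synthase (A_03722), the entry enzyme of the shikimate pathway, differed by 1.31 ± 0.09 on the log2 scale (SE, adjusted p = 0.0122), shikimate dehydrogenases by 1.56 ± 0.17 (DC_00801, adjusted p = 0.0391) and 1.30 ± 0.11 (C_02628, adjusted p = 0.0182), and a prephenate dehydratase (A_00576), on the branch to phenylalanine, by 1.04 ± 0.13 (adjusted p = 0.0466). Aquaporins, the water channels of membranes, were higher by 2.63 (A_01884, adjusted p = 0.00374), 2.55 (C_06040, adjusted p = 0.00374) and 2.10 (C_00247, adjusted p = 0.00783). A dehydrin (A_10349), a protein of drying tissue, was higher by 2.62 (adjusted p = 0.0324) and galactinol synthase (A_13575), the entry enzyme of raffinose sugars, by 1.66 (adjusted p = 0.026).

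Other genes called under that setting went both ways. Asparagine synthase (A_03561), which stores nitrogen as asparagine, was higher by 4.25 ± 0.26 (adjusted p = 0.0144) and cystathionine gamma lyase (A_09745) by 2.37 ± 0.18 (adjusted p = 0.0149). Pyruvate decarboxylases, enzymes of fermentation, were higher by 1.38 (A_04386, adjusted p = 0.0149) and 1.37 (C_00266, adjusted p = 0.0115). An acetyltransferase of hexenol (A_12294), which makes a green leaf volatile, was higher by 1.73 (adjusted p = 0.0466), an annexin (A_00615) by 1.79 (adjusted p = 0.00776), and hydrolases that free auxin from amino acids by 1.99 (A_15541, adjusted p = 0.034) and 1.05 (C_03411, adjusted p = 0.0379). On the lower side were a beta-glucosidase (DC_00592, -1.79, adjusted p = 0.0235), gibberellin-regulated proteins (C_04177, -1.57, adjusted p = 0.0466, and A_16974, -1.04, adjusted p = 0.026), a germin-like oxalate oxidase (A_10588, -1.15, adjusted p = 0.0412) nitrate reductase (C_05375, -0.95, adjusted p = 0.0482) and cysteine synthase (A_01179, -0.75, adjusted p = 0.0466). None of these genes passed in the fit on treatment alone. Without a block, A_03722 also passed in limma with trend and robust moderation (adjusted p = 0.027) and with array weights (0.026). For A_09745 another probe than the one given above passed under these settings (0.0441 and 0.0347). A_00615 passed with array weights (0.0485), and A_01884 with the block and both arrays of Friesland left out (0.0308). No enrichment of these groups was tested.

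The ribosomal protein list had a positive and the photosynthesis list a negative median with eggs, and a hypothesis was that cytosolic and plastid ribosomal proteins move apart. The 143 genes of cytosolic 40S and 60S subunits had a median of 0.306, with 132 positive and 11 negative (camera adjusted p = 1.26e-13, and adjusted p = 0.269 with an estimated correlation). The 103 genes of plastid-type 30S and 50S subunits had a median of -0.201, with 45 positive and 58 negative (camera adjusted p = 0.0702, and adjusted p = 0.269 with an estimated correlation). The plastid median stayed negative under 4 other scalings (-0.212 to -0.109) and in each population (-0.101 in Erkner, -0.195 in Friesland, -0.212 in Siethen), where the cytosolic medians were 0.127, 0.168 and 0.57. The plastid members did not pass the test, so the data do not decide whether the plastid side may truly be lower.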
